A study of Mus musculus with 9 samples.

How the data were processed

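RNA was measured on an Affymetrix whole-transcript array in mouse macrophages that lack the transcription factors MafB and c-Maf (Maf-DKO). There were 9 arrays in 3 groups: untreated proliferating cells, cells given 10 mM nicotinamide (NAM) for 1 h, and cells given 10 mM NAM for 10 h. Each group held 3 arrays, from the separately derived clones 01, 11 and 14 that the labels name as biological replicates, so each clone gave 1 array per group. The labels give 200 ng of input RNA and an RNA integrity number above 8.9 for every array. They do not say how long after the last medium renewal the untreated wells were harvested. The number of arrays limits the precision: the median standard error of a log2 change was 0.05.

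Per the labels, the authors processed the arrays with RMA in the affy package, version 2.9. The deposited values are log2 probe-set summaries on the RMA scale, with 1 column per array and no pooling of replicates. The values ran from 3.51 to 14.22 and the array medians from 6.27 to 6.37. The chip definition and the genome build behind the annotation are not given in the sources used here. The gene of each probe set came from the table supplied with the deposited values. Of 34760 probe sets, 21640 carried exactly 1 gene symbol, 1321 carried several and 11799 carried none. A gene was represented by its brightest probe set, by the mean over all 9 arrays, among those with exactly 1 symbol, which left 19937 genes. Mafb is absent from the annotation and Cdkn1a appears only on a probe set that lists more genes than 1, so neither was analysed here. No filter on dim probe sets and no further scaling was applied in the main analysis.

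The tests used limma 3.58.1 in R 4.3.3. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. A linear model of group means was fitted to all 9 arrays, the 3 groups sharing 1 estimate of the spread, with moderated statistics (eBayes). The 3 contrasts were 1 h against untreated, 10 h against untreated and 10 h against 1 h. Every p printed for a gene is 2-sided and adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at 0.05. The contrast of 10 h with 1 h is also the test of whether the change from untreated differed between the times.

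Gene lists were tested with camera from limma, with its preset inter-gene correlation of 0.01 and adjustment over the 41 lists within a comparison. The lists were written from textbook knowledge before the data were examined, as were the contrasts, the thresholds and all alternatives other than those named as later additions. They hold 791 distinct genes, of which 732 were measured, and 6 of them hold markers of other cell types. Each list was also tested with an inter-gene correlation estimated from the data and with fry, which tests a list's own members without comparing them with other genes. Members called are counted over all genes tested and adjusted over the list alone.

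Named genes were chosen by a rule fixed before the data were examined. For 1 h and for 10 h against untreated it takes the 10 largest rises and the 10 largest falls among called genes whose same-clone differences pointed the same way in 3 of 3 clones. For 10 h against 1 h it takes the first 3 each way. For each list named it takes up to 4 called members with the largest change. Predicted genes, small RNAs, chemosensory receptors and immunoglobulin or T cell receptor segments were counted but not named. Genes of interest named whatever their values were Mafb, Maf, Sirt1, Nampt, Myc, Klf2, Klf4, Ccnd1, Cdkn1a, Cdkn1b, E2f1, Mki67 and Csf1r.

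Whether clones pair the arrays was checked on residuals after removal of group means. The 9 correlations between arrays of the same clone ran from 0.361 to 0.628 and the 18 between different clones from -0.532 to 0.001, so the numbers pair the arrays at the limit of 0.1 fixed in advance. The main fit, fixed before, has no block, and a fit with the clone as a replicate block was run beside it. Its value stands beside a result where it ends or adds a call or moves a count by over 1.5 times. Genes differing between clones were tested with limma's F test in the fit with group and clone. Agreement of the 1 h and 10 h changes was set against 100 simulations of unchanged groups that share the untreated arrays.

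The other alternatives were quantile normalization, median centring, a filter on dim probe sets, a robust eBayes with trend, array weights, fits on the 2 groups compared, the mean of a gene's probe sets, every probe set tested singly, an adjusted p under 0.01, a fold of at least 1.5, camera on ranks, and leaving out each array or clone. The pipeline was tested on simulated data. Of 50 genes changed by 1 log2 unit at each of the 3 contrasts, all 50 were recovered. Of 50 changed by 0.3, 36, 36 and 35 were recovered, with 8, 2 and 14 false calls among 19937 genes in all. The simulated noise was independent between genes and arrays and held no differences between clones, so the real arrays may give other rates.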

Results

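The series asks how Maf-DKO macrophages, which keep dividing in culture without the transcription factors MafB and c-Maf, respond to nicotinamide, the amide form of vitamin B3. NAM is a precursor of NAD and an inhibitor of sirtuin deacetylases. RNA was profiled in untreated cells and after 1 h and 10 h of 10 mM NAM, with 3 arrays per group from clones 01, 11 and 14. Values below are log2 RMA expression, as mean ± SD over n = 3 arrays. Arrays of the same group correlated at 0.995 to 0.998 across probe sets. On a principal component analysis the first component carried 52% of the variance and the next 17.1%.

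Most genes fixed in advance as of interest were not called at either time. Maf read 9.38 ± 0.10 in untreated cells, 9.35 ± 0.07 at 1 h and 9.45 ± 0.07 at 10 h. The probes may lie outside the deleted part of the gene, and no wild-type array allows a comparison. Sirt1, a nuclear sirtuin, read 8.41, 8.34 and 8.34 and was not called (adjusted p = 0.884 at 1 h and 0.502 at 10 h). Nampt, which salvages nicotinamide into NAD, read 10.90, 10.89 and 10.86. The M-CSF receptor Csf1r read 12.88, 12.93 and 12.88, and the proliferation marker Mki67 read 12.43, 12.41 and 12.38. E2f1 and Klf2 were not called at either time. Myc, a driver of growth genes, read 11.01 ± 0.24 untreated, 9.98 ± 0.25 at 1 h and 10.44 ± 0.39 at 10 h. Its log2 changes of -1.02 and -0.57 were lower in 3 of 3 clones but not called (adjusted p = 0.0834 and 0.114), and were called with the clone as a replicate block (adjusted p = 0.00822 and 0.0121).

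After 1 h of NAM the called changes were few and mostly downward. Ch25h, which encodes cholesterol 25-hydroxylase, fell from 10.18 ± 0.20 to 7.62 ± 0.36, a 5.92-fold drop (log2 change -2.57, SE 0.28, adjusted p = 0.0059). Kcnj2, an inward-rectifier potassium channel, fell 4.22-fold from 9.29 ± 0.21 to 7.22 ± 0.11 (adjusted p = 0.000777). Rnd3, an atypical Rho GTPase, fell 3.08-fold from 9.56 ± 0.14 to 7.93 ± 0.10, and the transcriptional repressor Bcl6 fell 3.02-fold from 9.65 ± 0.13 to 8.06 ± 0.10 (adjusted p = 0.000148 and 0.000778). H3c4, a histone H3 gene, rose 3.77-fold from 6.25 ± 0.27 to 8.17 ± 0.20 (SE 0.15, adjusted p = 0.00156), and the kinase gene Pim1 rose 1.84-fold from 9.86 ± 0.27 to 10.74 ± 0.15 (SE 0.13, adjusted p = 0.0255). Each of these changes had the same direction in 3 of 3 clones, as the naming rule requires. In untreated cells H3c4 read below the lowest array median of 6.27, so its fold rests on a dim probe set.

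The next largest falls at 1 h were in Ptger4, the EP4 receptor for prostaglandin E2 (2.75-fold), Plau, the protease urokinase (2.46-fold), the growth factor gene Pdgfb (2.45-fold), the chemokine gene Ccl3 (2.15-fold), the stress-response factor Atf3 (2.07-fold) and Rasgef1b, a Ras-family exchange factor (1.85-fold), with adjusted p from 0.00411 to 0.0431. The other rises were smaller. The histone genes H2bc8 and H1f2 rose 1.75-fold and 1.32-fold, and the zinc finger genes Zfp799 and Zfp407 rose by log2 changes of 0.57 and 0.29. Gnrh1 rose by 0.40, Dnajb9, an ER co-chaperone, by 0.31, Arid5a, an RNA-binding regulator of cytokine mRNAs, by 0.28 and Ccnt1, the cyclin of P-TEFb, by 0.21. Histone genes have near-identical copies, so which copy a probe set reads is uncertain. Klf4 fell by 0.38 on the log2 scale (adjusted p = 0.0317), while Klf2 was not called.

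**Figure D1:**
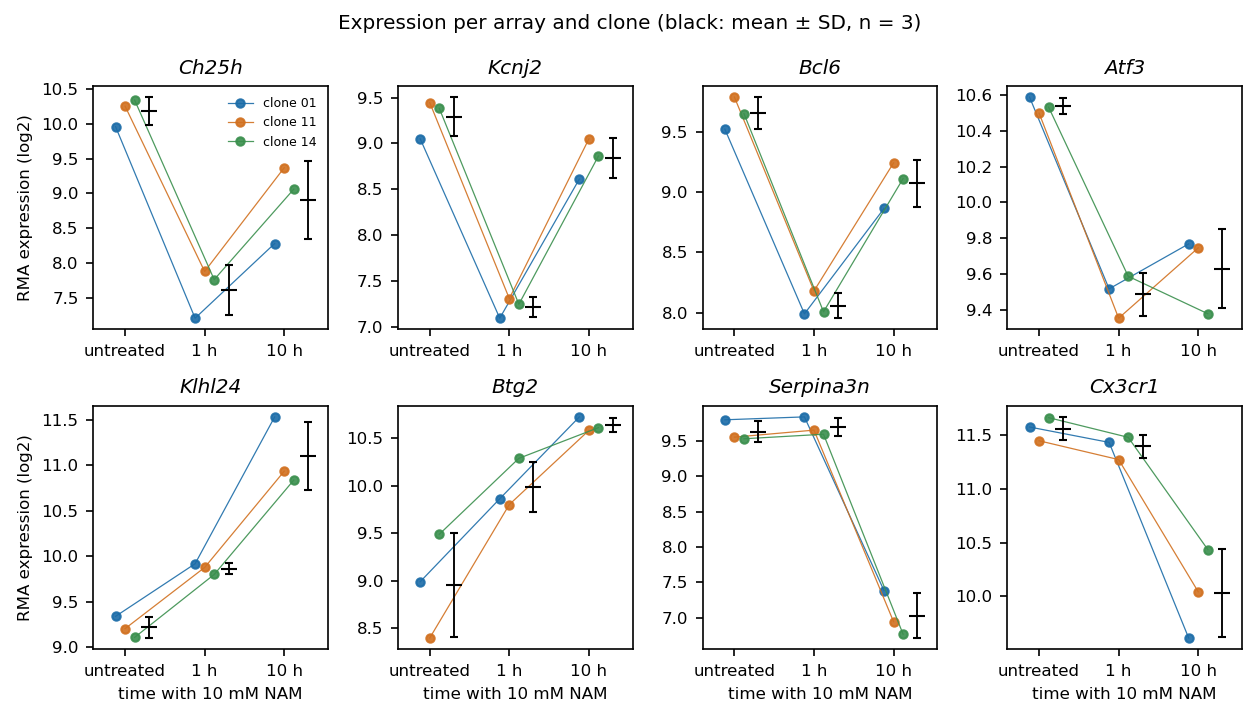
Log2 RMA expression (vertical axes) of 8 named genes in untreated cells and after 1 h and 10 h of 10 mM NAM (horizontal axes); coloured points are single arrays joined by clone, and black marks are the mean ± SD of 3 arrays. Ch25h, Kcnj2 and Bcl6 are lowest at 1 h and partly back at 10 h, Atf3 stays low, and Klhl24, Btg2, Serpina3n and Cx3cr1 are furthest from untreated at 10 h.

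In all, 162 of 19937 genes were called at 1 h, 11 higher and 151 lower (93.2% lower), and 39 of them changed at least 1.5-fold. A fit with the clone as a replicate block called 513 genes, 64 higher and 449 lower, among them all 162. The count rested on few arrays: it was 100, 54 and 64 without the untreated array of clone 01, 11 or 14, 94, 55 and 62 without the 1 h array of those clones, and 37, 0 and 16 without the whole of clone 01, 11 or 14. Without clone 11, limma gave 914 genes at an unadjusted p under 0.05, and the blocked fit called 10.

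Of the 41 gene lists, 5 were called at 1 h. Replication-dependent histone genes had a positive change, called or not, in 12 of 12 measured members (median log2 change 0.18, adjusted p = 5.97e-08). H1f2 was the 1 member called over all genes, and 5 were called when adjusted over the list alone. H3c4 and H2bc8 are outside that list. Small RNAs without a poly(A) tail had a median log2 change of 0.11 over 63 genes at 1 h, with 0 called by limma. Genes of oxidative phosphorylation, the respiratory chain, had a median of 0.06 (adjusted p = 0.000906), and those of the lysosome and autophagy a median of 0.05 (adjusted p = 0.0138), with 0 members called over all genes or adjusted over the list alone. NF-kB inflammatory genes had a median of -0.09 (adjusted p = 0.00696), with Ccl3 called lower and 4 lower adjusted over the list alone. Mitosis genes had a median of -0.05 (adjusted p = 0.00993), with 0 members called over all genes and 1 adjusted over the list alone. Single arrays moved these small medians by over 1.5 times. That of the NF-kB genes was -0.158, -0.205 and -0.007 without untreated clone 01, 11 or 14, and -0.053 and -0.192 without 1 h clone 11 or 14. That of mitosis was -0.094 and -0.008 without untreated clone 01 or 14, and -0.022 and -0.075 without 1 h clone 01 or 14. In the same 4 fits that of lysosome and autophagy was 0.10, 0.031, 0.022 and 0.077. Oxidative phosphorylation had 0.036 without untreated clone 14 and 0.029 without 1 h clone 01. None of the 5 calls held with an estimated correlation: adjusted p = 0.446 with an estimated correlation for the histones and 0.988 for each of the others, and fry called 0 lists (4 at an unadjusted p under 0.05, and 2 by camera with an estimated correlation). With the clone as a replicate block 10 lists were called, the 5 added being FoxO targets and M-CSF and MAPK feedback genes (lower) and the LXR, fatty acid synthesis and ATF4 lists (higher), with adjusted p from 0.032 to 0.0475. With that block and an estimated correlation camera called 0, or 3 at an unadjusted p under 0.05, and the adjusted p of the 10 ran from 0.147 to 0.984. Targets of FoxO, transcription factors active when growth signalling is low, were not called without the block (adjusted p = 0.119), although Bcl6, Cited2 and S1pr1 fell by log2 changes of -1.59, -0.84 and -0.68.

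After 10 h of NAM the changes were many and ran both ways. Klhl24, a ubiquitin ligase adaptor, rose 3.69-fold from 9.22 ± 0.12 to 11.10 ± 0.38 (SE 0.16, adjusted p = 0.000208). Pdcd4, an inhibitor of translation initiation, rose 3.64-fold from 7.76 ± 0.20 to 9.62 ± 0.64, and the antiproliferative gene Btg2 rose 3.20-fold from 8.96 ± 0.55 to 10.64 ± 0.07 (adjusted p = 0.00241 and 0.00222). At 1 h Klhl24 and Btg2 had log2 changes of 0.65 and 1.02, not called (adjusted p = 0.158 and 0.136), but called with the clone as a replicate block (adjusted p = 0.0273 for each). Serpina3n, a serine protease inhibitor, fell 6.03-fold from 9.62 ± 0.15 to 7.03 ± 0.32 (log2 change -2.59, SE 0.15, adjusted p = 7.26e-05). Cd300e, an activating receptor of myeloid cells, fell 3.96-fold from 9.72 ± 0.53 to 7.73 ± 0.41, and Lpl, lipoprotein lipase, fell 3.57-fold from 12.13 ± 0.37 to 10.29 ± 0.64 (adjusted p = 0.00347 and 0.00563).

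The remaining largest rises were Abca6, a lipid transporter family member (2.74-fold), Crebrf, a regulator of stress and energy balance (2.61-fold), Trp53inp1, a p53-inducible stress gene (2.60-fold), Ypel3 (2.56-fold), Fbxl20 (2.50-fold), Pcmtd2 (2.44-fold) and Mxd4, a Max partner that opposes Myc (2.39-fold), with adjusted p from 0.000221 to 0.0147. Abca6 read 5.53 in untreated cells, below the lowest array median of 6.27, so its fold rests on a dim probe set. The remaining largest falls were Bex6 (3.42-fold), the interleukin-21 receptor Il21r (3.40-fold), Scimp, an adaptor of immune receptors (3.38-fold), Cd244a, a SLAM-family receptor (3.24-fold), Cd24a (3.05-fold), Plau (3.0-fold) and Cx3cr1, the fractalkine receptor (2.89-fold), with adjusted p from 2.79e-05 to 0.0224. Il21r had a log2 change of -0.32 at 1 h (adjusted p = 0.259, or 0.0217 with the clone as a replicate block). All of these 10 h changes had the same direction in 3 of 3 clones, as the naming rule requires. Cyclin D1 (Ccnd1) fell 1.57-fold from 13.24 ± 0.10 to 12.59 ± 0.32 (adjusted p = 0.0132) and Cdkn1b, the CDK inhibitor p27, rose 1.41-fold from 9.93 ± 0.02 to 10.42 ± 0.13 (adjusted p = 0.00157).

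Genes of ribosome biogenesis and other Myc targets formed the most uniform group at 10 h: 27 of 29 fell, and 28 when adjusted over the list alone, with a median log2 change of -0.59 (adjusted p = 2.5e-26, and adjusted p = 0.16 with an estimated correlation). Dkc1, a pseudouridine synthase, fell by 1.18 on the log2 scale, Srm, the polyamine enzyme spermidine synthase, by 1.03, and the nucleolar proteins Gnl3 and Nop58 fell by 0.97 and 0.90. Genes of the unfolded protein response fell in 12 of 17 members and rose in 1, with the same counts adjusted over the list alone (median -0.40, adjusted p = 2.3e-09): the ER folding genes Pdia6, Hspa5 and Manf and the factor Xbp1 had log2 changes of -0.59, -0.55, -0.50 and -0.57, and Dnajb9 rose by 0.24. Glycolysis genes fell in 9 of 14 members, 10 adjusted over the list alone (median -0.29, adjusted p = 4.94e-09), among them the lactate exporter Slc16a3 (-0.96), hexokinase Hk2 (-0.68), Tpi1 (-0.68) and the glucose transporter Slc2a1 (-0.54). These last lists were the 2 whose calls held with an estimated correlation (adjusted p = 0.0324 and 0.0479). With the clone as a replicate block as well, they had adjusted p = 0.164 and 0.251.

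Further lists were called lower with smaller medians. Oxidative phosphorylation genes fell in 6 of 24 members, 10 adjusted over the list alone (median -0.11, adjusted p = 0.000132, and adjusted p = 0.7 with an estimated correlation), with Ndufa5 at -0.40, Cycs at -0.31 (its other probe sets from -0.613 to 0.001) and Ndufs1 at -0.30. Heat shock genes fell in 6 of 14 and rose in 1, or 9 and 2 adjusted over the list alone (median -0.20, adjusted p = 0.00364, and adjusted p = 0.586 with an estimated correlation), with the mitochondrial chaperonin Hspd1 at -0.48 and Hspa4l at 0.38. Interferon response genes fell in 4 of 25, or 6 with 1 rise adjusted over the list alone (median -0.21, adjusted p = 0.00121, and adjusted p = 0.704 with an estimated correlation): Rtp4, Ifit1, Ifit3 and Oas1a had log2 changes of -1.24, -1.22, -1.11 and -0.64. Chemokine receptor and adhesion genes fell in 8 of 24 and rose in 1, or 9 and 1 adjusted over the list alone (median -0.16, adjusted p = 0.00121, and adjusted p = 0.417 with an estimated correlation). Besides Plau and Cx3cr1, the urokinase receptor Plaur fell by 0.75 and the chemokine receptor Cxcr4 rose by 1.00. The interferon median was -0.323 without untreated clone 11, -0.389 without 10 h clone 01 and -0.448 without all of clone 01. That of oxidative phosphorylation was -0.075 without untreated clone 01 and -0.070 without 10 h clone 14, and that of chemokine receptors and adhesion was -0.094 without untreated clone 14.

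Of 18 CDK inhibitor and growth arrest genes 10 rose and 1 fell at 10 h, with the same counts adjusted over the list alone (median 0.46, adjusted p = 0.00136, and adjusted p = 0.217 with an estimated correlation). Besides Btg2 and Mxd4 the largest were Ccng2 (1.16) and Gadd45a (0.97), and the CDK4/6 inhibitor Cdkn2d fell by 0.27. DNA replication genes fell in 7 of 31 and rose in 1, or 11 and 1 adjusted over the list alone (median -0.15, adjusted p = 0.00317, and adjusted p = 0.824 with an estimated correlation), with Gins1 at -0.63 and the helicase subunits Mcm2, Mcm6 and Mcm3 at -0.46, -0.41 and -0.41. E2F and G1/S genes fell in 4 of 24, also 4 adjusted over the list alone (median -0.10, adjusted p = 0.0295), with the phosphatase Cdc25a at -0.44. Mitosis genes fell in 3 of 33, or 2 adjusted over the list alone (median -0.09, adjusted p = 0.00667), with Cdc20 at -0.26. For each of these lists the adjusted p was 0.824 with an estimated correlation. In the list of G1 cyclins and the Myc family 3 of 10 genes fell and 1 rose, or 5 and 1 adjusted over the list alone (median -0.20, adjusted p = 0.0371, and adjusted p = 0.401 with an estimated correlation): Ccnd1, Max (-0.26) and Cdk4 (-0.19) were lower and Mnt, a repressor that competes with Myc for Max, was higher (0.21). The E2F median was -0.032 and -0.159 without 10 h clone 01 or 11 and -0.148 without all of clone 11, and that of DNA replication was -0.061 without 10 h clone 01. Mitosis had medians of -0.136 and -0.039 without untreated clone 01 or 14, and of -0.142 and -0.048 without all of clone 01 or 14.

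Besides the growth arrest genes, 4 lists were called higher at 10 h. FoxO targets rose in 7 of 20 members and fell in 1, or 8 and 2 adjusted over the list alone (median 0.21, adjusted p = 0.0347, and adjusted p = 0.417 with an estimated correlation). Ccng2, the insulin receptor Insr (0.59) and the glucocorticoid-induced gene Tsc22d3 (0.59) were higher and Bcl6 was lower (-0.58). With the clone as a replicate block the list had an adjusted p = 0.0623. Immediate early genes rose in 8 of 30 and fell in 2, or 14 and 2 adjusted over the list alone (median 0.26, adjusted p = 0.0347, and adjusted p = 0.707 with an estimated correlation), with Egr2 at 0.80 and Fosb at 0.73 and Atf3 at -0.90. Circadian clock genes rose in 5 of 16, or 6 adjusted over the list alone (median 0.10, adjusted p = 0.0403, and adjusted p = 0.7 with an estimated correlation), with Dbp at 0.70, Per3 at 0.68 and Nr1d2 at 0.53. With the clone as a replicate block the adjusted p was 0.0994. Replication-dependent histone genes rose in 3 of 12, also 3 adjusted over the list alone (median 0.15, adjusted p = 0.0478, and adjusted p = 0.7 with an estimated correlation), with H1f3 at 0.97 and H2bc21 at 0.54. Their median was 0.093 without untreated clone 11, 0.10 and 0.093 without 10 h clone 11 or 14, and 0.083 without all of clone 11, and the FoxO median was 0.118 without all of clone 11.

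Genes of NAD metabolism and the sirtuins, the direct setting of the treatment, were not called as a list at 10 h (median 0.05, adjusted p = 0.171), although 5 of 23 rose and 1 fell, or 6 and 1 adjusted over the list alone. The mitochondrial sirtuins Sirt4 and Sirt3 rose by 0.50 and 0.42, Nmnat3, an NAD-synthesising enzyme, rose by 0.27, and Bst1, which consumes NAD, fell by 0.32. None of the 6 lists of markers of other cell types was called in any comparison. Their lowest adjusted p was 0.604 at 1 h and 0.398 at 10 h, both for stromal and fibroblast markers, and 0.521 for mast cell markers at 10 h against 1 h.

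**Figure D2:**
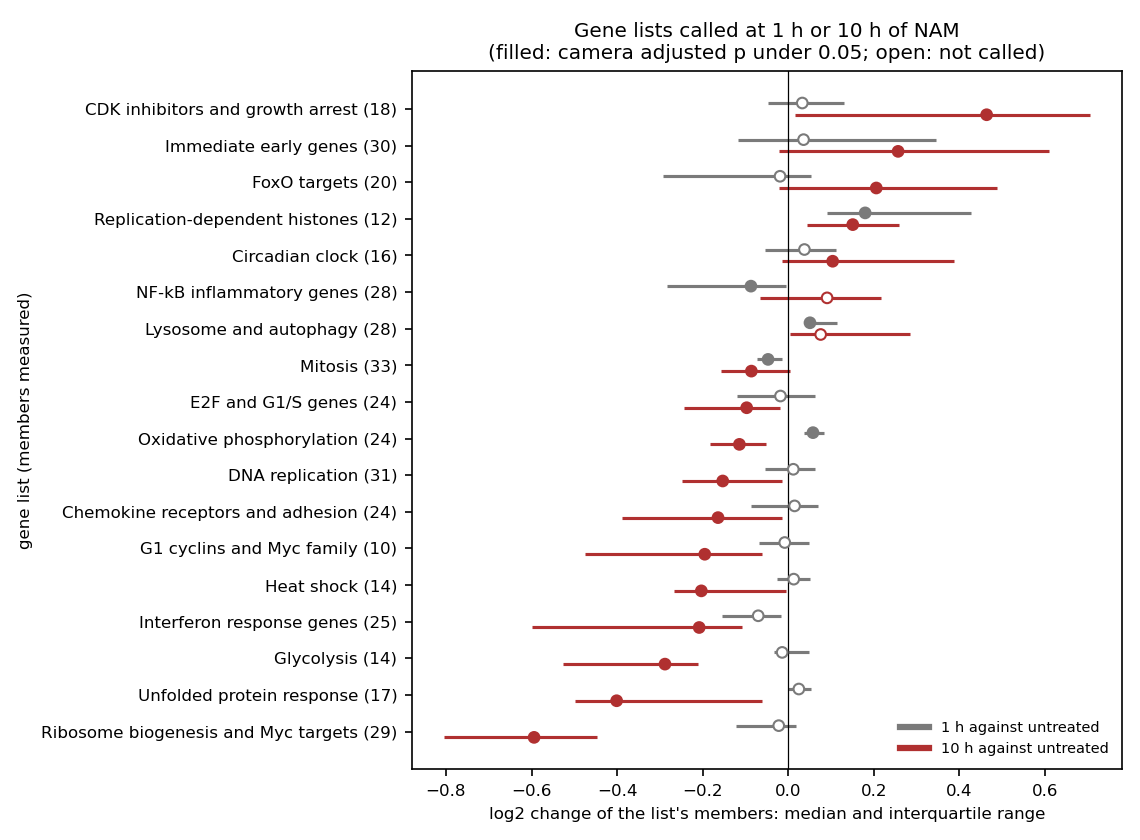
Median (points) and interquartile range (lines) of the log2 change of the members of each gene list called at 1 h (grey) or 10 h (red) against untreated; filled points passed the camera test and open points did not, and the number of members measured stands after each name. Ribosome biogenesis and Myc targets lie lowest at 10 h, at -0.59, and CDK inhibitor and growth arrest genes highest, at 0.46.

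In all, 3368 genes were called at 10 h, 1784 higher and 1584 lower (47% lower). After median centring of the arrays the split was 1050 higher and 1868 lower (64% lower), so which direction held more genes depended on the scaling. It also turned without clone 01 (898 higher, 1122 lower) and without clone 11 (425 higher, 603 lower). The share lower was 50.3% to 52.2% without the untreated array of clone 01, the 10 h array of clone 01 or that of clone 11, and 50.7% after quantile normalization. Of the 3368 genes, 472 changed at least 1.5-fold, 194 higher and 278 lower. The count fell to 2020 without clone 01 and 1028 without clone 11. Of 16 lists called, 6 were not called without the 10 h array of clone 01: E2F and G1/S genes (adjusted p = 0.293), circadian clock (0.167), DNA replication (0.0598), immediate early genes (0.0529), histones (0.0529) and G1 cyclins (0.0505).

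The contrast of 10 h with 1 h shows which genes moved between the times, from whatever cause. Serpina3n (6.33-fold), Cd300e (3.86-fold) and Lpl (3.32-fold) were lower at 10 h than at 1 h, with adjusted p = 6.53e-05, 0.00355 and 0.00707. Kcnj2 (3.08-fold), Abca6 (2.65-fold) and Pdcd4 (2.48-fold) were higher, with adjusted p = 0.000172, 0.00255 and 0.0118. Each had the same direction in 3 of 3 clones, as the naming rule requires. Abca6 read 5.575 at 1 h, below the lowest array median of 6.27, so its fold rests on a dim probe set. By 10 h Kcnj2 had returned most of the way to its untreated level but was still called lower (log2 change -0.45, adjusted p = 0.0487). That call was kept in 3 of 12 fits without an array or clone. Ptger4 was no longer called against untreated (log2 change -0.18, adjusted p = 0.633). Ch25h, Rnd3 and Bcl6 were also higher at 10 h than at 1 h, by log2 changes of 1.29, 0.86 and 1.01, and remained lower than untreated. H3c4 fell by 1.22 between the times. Plau, Pdgfb, Atf3 and Rasgef1b were lower than untreated at both times, with no called difference between them, except that Plau was lower at 10 h than at 1 h with the clone as a replicate block (log2 change -0.28, adjusted p = 0.0442, against 0.508 without it).

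Among the lists, 12 were called at 10 h against 1 h. Ribosome biogenesis and Myc targets (28 of 29 lower, 29 adjusted over the list alone, median -0.53, adjusted p = 1.03e-25, and adjusted p = 0.126 with an estimated correlation), unfolded protein response (12 of 17 lower, also 12 adjusted over the list alone, median -0.42, adjusted p = 2.85e-13) and glycolysis (11 of 14 lower, also 11 adjusted over the list alone, median -0.32, adjusted p = 1.4e-09) were again lowest, and the last pair held with an estimated correlation (adjusted p = 0.0125 and 0.0412), but not with the clone as a replicate block as well (adjusted p = 0.0801 and 0.167). FoxO targets rose in 9 of 20 members, or 11 with 1 fall adjusted over the list alone (median 0.39, adjusted p = 5.25e-05, and adjusted p = 0.122 with an estimated correlation). CDK inhibitor and growth arrest genes rose in 8 of 18, also 8 adjusted over the list alone (median 0.35, adjusted p = 0.00145, and adjusted p = 0.183 with an estimated correlation). NF-kB inflammatory genes rose in 5 of 28, or 6 adjusted over the list alone (median 0.23, adjusted p = 0.0275), and immediate early genes in 5 of 30, or 6 adjusted over the list alone (median 0.16, adjusted p = 0.0314), both with adjusted p = 0.808 with an estimated correlation. In the fit with the clone as a replicate block, E2F and G1/S genes (median -0.09, adjusted p = 0.0215) and G1 cyclins and the Myc family (median -0.14, adjusted p = 0.0428) were called lower as well. They were not called with an estimated correlation in that fit (adjusted p = 0.644 and 0.399). The median of the growth arrest genes was 0.195 without 10 h clone 01 and 0.190 without all of clone 01, and that of the NF-kB genes 0.139 without 1 h clone 11. Immediate early genes had 0.243 without 1 h clone 14, 0.103 and 0.251 without 10 h clone 11 or 14, and 0.286 without all of clone 14.

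The other lists called at 10 h against 1 h were lower. Oxidative phosphorylation genes fell in 10 of 24 members, or 11 adjusted over the list alone (median -0.18, adjusted p = 1.68e-08). Heat shock genes fell in 6 of 14 and rose in 1, or 7 and 1 adjusted over the list alone (median -0.19, adjusted p = 0.001). Chemokine receptor and adhesion genes fell in 7 of 24, or 8 adjusted over the list alone (median -0.18, adjusted p = 0.001). For each of these lists the adjusted p was 0.4 with an estimated correlation. Interferon response genes fell in 4 of 25 and rose in 1, or 5 and 2 adjusted over the list alone (median -0.18, adjusted p = 0.00841, and adjusted p = 0.808 with an estimated correlation). DNA replication genes fell in 9 of 31, or 10 adjusted over the list alone (median -0.07, adjusted p = 0.0039, and adjusted p = 0.915 with an estimated correlation). Without the 10 h array of clone 01 the median was 0.007 and the list was not called. It was -0.138 and -0.017 without 1 h clone 01 or 14, and -0.114 without 10 h clone 11 or 14. In all, 3551 genes differed between the times, 1953 higher and 1598 lower at 10 h (45% lower), or 1295 higher and 1659 lower after median centring (56.2% lower). The count was 2252 without clone 01 and 1046 without clone 11, where 465 were higher and 581 lower.

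Of the 151 genes called lower at 1 h, 56 were also lower at 10 h, 19 were higher and 76 were not called at 10 h, and 103 were higher at 10 h than at 1 h. Their median log2 change went from -0.41 at 1 h to -0.10 at 10 h. Independent lists would share 12 genes lower at both times, 13.5 lower at 1 h and higher at 10 h, and 0.984 higher at both. Both calls rest on the same untreated arrays, which raises the number lower at both times and lowers the number that turned. No value for the overlap that allows for the shared arrays was computed. Of the 11 genes called higher at 1 h, 8 were also higher at 10 h and 3 were not called. H2bc8 was called higher at 10 h with the clone as a replicate block (log2 change 0.35, adjusted p = 0.00161) and Zfp407 lower (-0.14, adjusted p = 0.0192). The same 1 h arrays chose these genes and gave the contrast with 10 h, so some return toward the untreated level arises from the choice itself. Across all genes, which are not independent replicates, the 1 h and 10 h changes correlated at Pearson r = 0.297 and Spearman rho = 0.238. Unchanged groups simulated against the same untreated arrays gave r = 0.501 and a covariance of 0.0036, or 0.0018 with the spread left after the clones, against 0.0067 observed, so the correlation lay below and the covariance above what the shared arrays alone gave.

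**Figure D3:**
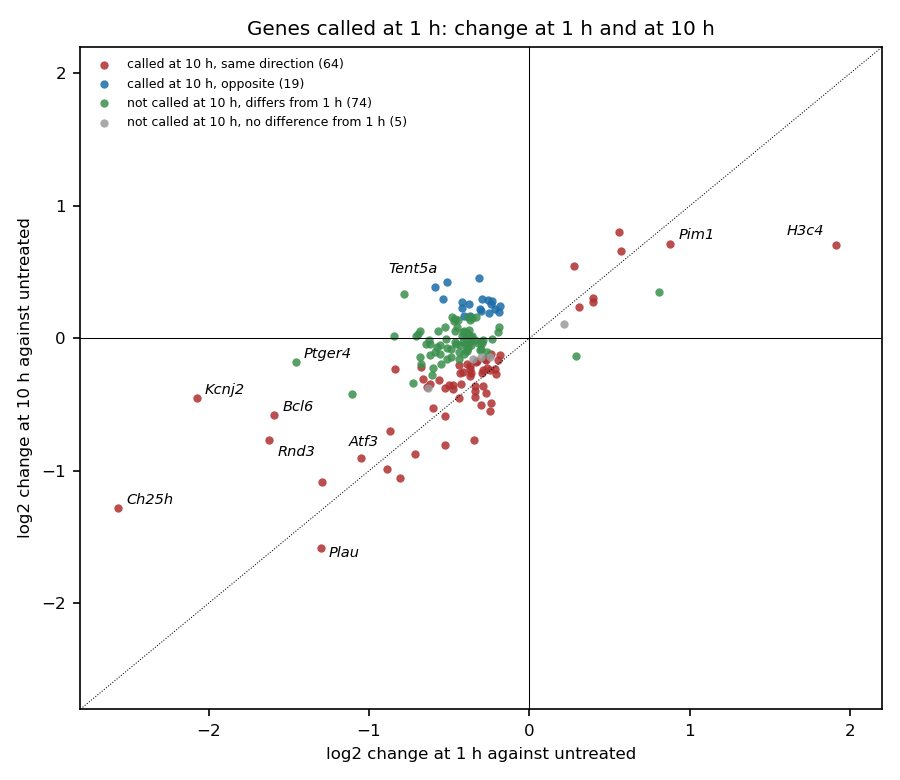
Log2 change at 1 h (horizontal axis) and at 10 h (vertical axis) against untreated for the 162 genes called at 1 h, coloured by their call at 10 h; the dotted line marks equal change. In all 64 genes were called in the same direction at 10 h, 19 in the opposite direction, and 74 were not called at 10 h but differed from 1 h.

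The clones differed from each other in 1436 genes at an adjusted p under 0.05 in limma's F test. Ranges of clone means were ranked only among the called genes with the lowest p in that test. The widest there, picked after the values were seen, were in Gsta3, a glutathione transferase (2.16 log2 units), the chemokine gene Ccl22 (2.03) and Prkcb, a protein kinase C gene (1.73). With 1 array per clone and group, whether clones respond differently to NAM was not tested.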

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

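The tests chosen only after the result was seen were those of an offset between arrays, of medium renewal, of spent medium and of S phase; the tests of brightness, of small RNAs and of other groupings of the arrays were planned.

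The first pattern is that called genes at 1 h were mostly lower (151 of 162). The median change of all genes was -0.0018, against -0.413 for the called falls. RMA brings the arrays to a common distribution, so this median cannot test for a distortion left by the normalization. The direction did not rest on a uniform offset of the deposited values, as median centring gave 163 lower and 8 higher. Uncalled genes matched in brightness had a median of 0.003, so in the deposited values genes as bright did not fall alike. RMA and the choice of uncalled genes hold this median near 0, so it cannot exclude a distortion tied to brightness. Medium renewal or harvest time stays open and cannot be told apart from NAM, since the untreated wells' time after renewal is not given; immediate early genes, which answer to fresh medium, had a median of 0.036 with members on both sides. Of the 10 groupings of the 6 arrays into 3 and 3, the real one called 162 genes and the highest other 0, too few groupings for a share under 0.05, and among the 4 that part the clones as the real one does the blocked fit called 513 against 0. The 4 groupings are too few for such a share as well. The other groupings mix treated and untreated arrays, so a real difference enters their spread and lowers their counts. An early response to NAM itself remains a hypothesis, untested against medium renewal.

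The next pattern is the fall of ribosome biogenesis genes at 10 h (median -0.594). Of 10000 random lists matched in brightness, 0 had a median as low, the lowest being -0.186. In the deposited values the fall thus went beyond that of genes as bright. RMA holds such medians near 0, so they cannot exclude a distortion tied to brightness that it left. Older or spent medium in the 10 h wells cannot be told apart from NAM, because the labels do not give the medium's age in the untreated wells; targets of ATF4, which respond to amino acid shortage, had a median of 0.033 with members both ways. The real groupings called 3368 genes at 10 h against untreated and 3551 against 1 h, with a highest other of 0 in both, again 1 of 10 each and too few for a share under 0.05; the blocked fits called 4967 and 5209, and 0 in the other groupings that part the clones alike. Here too the other groupings mix the groups compared, which lowers their counts, and those that part the clones alike are too few. A response to NAM is the biological explanation the design names and remains untested against the medium.

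The last pattern is the rise of replication-dependent histone genes at 1 h (median 0.18). Uneven recovery of RNAs without a poly(A) tail may account for part of it: 63 small nucleolar and nuclear RNAs, which also lack a tail, had a median of 0.112 (SE 0.022, 50 of 63 positive, 0 called by limma), against 0.006 for other genes of their brightness, and by clone 0.106, 0.085 and 0.085. More cells in S phase cannot be told apart, since DNA replication genes had a median of 0.012 (SE 0.021) with members on both sides. Each SE of a median here came from resampling the genes of the set, which are not independent. It does not measure the spread between arrays. H3c4 rose by 1.92, but it lies outside the histone list, was picked as the largest rise at 1 h and rests on a dim probe set. Its rise therefore cannot be weighed against the median of the small RNAs. An effect of NAM on histone transcripts stays open beside uneven recovery and was not told apart from it.

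Expression at 10 h of NAM differed from that at 1 h in 30 of the genes named as largest changes or as of interest. The untreated arrays cancel in this contrast, so a changing response to NAM cannot be told apart from medium age or time in culture. The genes named as largest changes were picked on these same arrays. Log2 change at 10 h minus that at 1 h was negative for Serpina3n (-2.66), Cd300e (-1.95), Lpl (-1.73), Bex6 (-1.58), Scimp (-1.57), Cd24a (-1.53), Cd244a (-1.53), Il21r (-1.45), Cx3cr1 (-1.36), H3c4 (-1.22), Ccnd1 (-0.57), H2bc8 (-0.46) and Zfp407 (-0.43). It was positive for Kcnj2 (1.62), Abca6 (1.41), Pdcd4 (1.31), Mxd4 (1.31), Ch25h (1.29), Ptger4 (1.28), Klhl24 (1.24), Ypel3 (1.17), Pcmtd2 (1.16), Fbxl20 (1.09), Trp53inp1 (1.02), Bcl6 (1.01), Rnd3 (0.86), Ccl3 (0.68), Cdkn1b (0.49), Klf4 (0.44) and Arid5a (0.27). With the clone as a replicate block, the difference was also called for Crebrf (0.69, adjusted p = 0.00976), Btg2 (0.66, adjusted p = 0.026), Myc (0.46, adjusted p = 0.0295) and Plau (-0.28, adjusted p = 0.0442). Of the 30 genes, 12 kept the call in all 12 fits without an array or clone. That of Trp53inp1 was kept in 2 of 12, was lost after median centring (adjusted p = 0.0628) and in the fit on the 2 groups (adjusted p = 0.0923), and its value was 0.68 without the 10 h array of clone 01 (adjusted p = 0.09).

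Lists differed between the times as well. The median difference was -0.53 for ribosome biogenesis and Myc targets, -0.42 for the unfolded protein response, -0.32 for glycolysis, -0.19 for heat shock, -0.18 for interferon response genes, -0.18 for oxidative phosphorylation, -0.18 for chemokine receptors and adhesion and -0.069 for DNA replication. It was 0.39 for FoxO targets, 0.35 for CDK inhibitors and growth arrest, 0.23 for NF-kB inflammatory genes and 0.16 for immediate early genes. With an estimated correlation, the unfolded protein response and glycolysis were called (adjusted p = 0.0125 and 0.0412) and the other 10 were not (adjusted p from 0.122 to 0.915). Without single arrays or clones the median was 0.195 (10 h clone 01) and 0.190 (clone 01) for CDK inhibitors and growth arrest and 0.139 (1 h clone 11) for NF-kB. It ran from 0.103 (10 h clone 11) to 0.286 (clone 14) for immediate early genes, and from -0.138 (1 h clone 01) to 0.007 (10 h clone 01) for DNA replication. Among 13120 probe sets without a single gene symbol, which entered none of the comparisons of genes, limma called 11 higher and 3 lower at 1 h, 372 higher and 296 lower at 10 h, and 288 higher and 499 lower at 10 h against 1 h.

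For the differences between clones, 1 of 36 assignments of clone numbers within groups, the real one, called 1436 genes, and the highest other called 130. That share lies under 0.05 and argues against chance, but it is the lowest that 36 assignments allow. Other assignments also move differences between clones into the spread, which lowers their counts. The test cannot tell the clone from anything else that the arrays of 1 clone shared.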

How the results depend on the processing

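Of the alternatives here, leaving out a clone in the fit with the replicate block and joining that block to an estimated correlation were added after the data were seen. Among the genes named by the rule, no gene that was called reversed. Of 21 genes called at 1 h, among those named as largest changes or as of interest, 0 kept the call in every one of the 12 fits without an array or clone and 12 kept it under the 8 other settings; of 36 at 10 h, 13 and 32 did; of 30 at 10 h against 1 h, 12 and 28 did. Abca6 had 7 other settings, as the filter on dim probe sets removed it. Of the lists, 1 and 3 of 5 did at 1 h, 8 and 10 of 16 at 10 h, and 8 and 10 of 12 at 10 h against 1 h.

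At 1 h, the 162 genes became 513 with the replicate block, 438 with array weights, 92 with every probe set tested, 48 at an adjusted p under 0.01 and 39 at a fold of at least 1.5. The 5 lists became 10 with the replicate block, 3 with the filter on dim probe sets, and 0 with camera's estimated correlation or with fry (2 and 4 at an unadjusted p under 0.05). At 10 h, 3368 genes became 1829 at an adjusted p under 0.01 and 472 at a fold of at least 1.5. At 10 h against 1 h, 3551 became 1950 and 423. In each of these comparisons 2 lists were called with an estimated correlation. Across all 3 comparisons 0 were called when the replicate block was joined to it (3, 5 and 5 at an unadjusted p under 0.05 in camera). With fry, 11 lists were called at 10 h and 13 at 10 h against 1 h, beside 16 and 12 in the main test. Stricter thresholds lower counts by construction; otherwise the cause was not tested. The correlation of the changes was 0.318 after quantile normalization, against 0.297.

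Without single arrays or clones, the 1 h genes ran from 0 (without clone 11; 914 at an unadjusted p under 0.05 in limma) to 186: 100, 54 and 64 without untreated clone 01, 11 and 14, 94, 55 and 62 without 1 h clone 01, 11 and 14, and 37 and 16 without all of clone 01 or 14. The blocked fit gave 137, 10 and 62 without clone 01, 11 and 14. The 10 h genes ran from 1028 (without clone 11; 2020 without clone 01) to 3664, and those of 10 h against 1 h from 1046 (2252 without clone 01) to 3674, or up to 4185 and 4232 with the block. The cause was not tested. The 1 h lists ran from 1 (without untreated 14) to 8 (without untreated 01 or 1 h clone 14), with 2 without 1 h clone 01 and 3 without clone 14; the 10 h lists from 10 (without 10 h clone 01) to 16; those of 10 h against 1 h from 10 to 13; and the correlation from 0.236 to 0.375. The median of DNA replication at 10 h against 1 h ran from -0.138 to 0.007, reversed without 10 h clone 01; the cause was not tested.

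Calls of lists lost in some fits had adjusted p there of up to 0.736 (mitosis at 1 h, without untreated 14), 0.451 (NF-kB at 1 h, without untreated 14), 0.44 (lysosome at 1 h, without 1 h clone 01), 0.455 (circadian clock, without clone 01), 0.419 (mitosis at 10 h, without clone 14), 0.293 (E2F, without 10 h clone 01), 0.168 (FoxO, immediate early genes and histones at 10 h, each without clone 11) and 0.125 (G1 cyclins, quantile normalization). The paired fit kept the calls of 162 of 162, 3356 of 3368 and 3538 of 3551 genes; of the lists it ended FoxO targets (adjusted p = 0.0623) and the circadian clock (0.0994) at 10 h and added 5, 1 and 2 calls in the 3 comparisons. Signal over background was not analysed here, so what dim probe sets limit can be read only from the filter.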

Other observations

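The tests of the gene families below, picked by symbol, were all chosen after the results they follow were seen; the lists were fixed before.

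Several lists were not called at 10 h yet held large single changes. In macrophage identity genes, 4 of 27 fell and 2 rose, also adjusted over the list alone (median -0.03, adjusted p = 0.236): besides Cx3cr1, the Fc receptor Fcgr1 and the scavenger receptor Msr1 fell by 1.14 and 0.91 on the log2 scale, and the Fc receptor Fcgr3 rose by 0.47. Ciita, the master regulator of MHC class II genes, fell by 1.45 in the antigen presentation list, where 2 of 14 fell and 2 rose, or 3 and 2 adjusted over the list alone (adjusted p = 0.822). In the LXR and lipid efflux list the cholesterol exporters Abca1 and Abcg1 rose by 0.66 and 0.38 and Mylip by 0.49, while Nr1h3, which encodes LXR alpha, fell by 0.60 (3 higher and 1 lower of 12, also adjusted over the list alone; adjusted p = 0.388).

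In the lysosome and autophagy list 6 of 28 genes rose at 10 h and 2 fell, or 7 and 2 adjusted over the list alone (median 0.08), with the initiating kinase Ulk1 at 0.90, Wipi1 at 0.64, Gabarapl1 at 0.53 and Map1lc3b at 0.40. The list was not called (adjusted p = 0.073) but was with the clone as a replicate block (adjusted p = 0.00924). With an estimated correlation it was not called in either fit (adjusted p = 0.824 with an estimated correlation, and 0.466 with the block as well). Hypoxia and HIF targets fell in 5 of 19 and rose in 2, or 6 and 2 adjusted over the list alone (median -0.14, adjusted p = 0.073), with P4ha1, a collagen prolyl hydroxylase, at -0.61, Pdk1 at -0.47 and Mxi1 at 0.56.

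Several Toll-like receptors, which sense microbial products, and their adaptors were among the early falls. Of 15 measured members picked by symbol, 7 were called lower at 1 h and 0 higher, against 0.114 expected from an even spread of the falls (2-sided Fisher's exact test, p = 7.6e-12); the family was looked at because some members were among the falls, and its genes are not independent, so this p overstates the evidence. The comparison was with all other genes tested, without a filter on dim probe sets. Genes too dim to show a fall would lower the expected number. The 7 called lower were Tlr4 (-0.42), Tlr9 (-0.36), Tlr13 (-0.25), Myd88 (-0.29), Ticam1 (-0.42), Ticam2 (-0.43) and Tirap (-0.47), named after their values were seen. The median of the family was -0.33 at 1 h and -0.03 at 10 h, and 4 members were called lower at 1 h after median centring and 10 with the clone as a replicate block. At 10 h 5 members were lower than untreated and 2 higher: of the 7, Tlr13 (-0.55), Ticam2 (-0.27), Tlr9 (-0.26) and Myd88 (-0.24) were still lower, Tlr4 (0.23) and Ticam1 (0.27) were higher and Tirap was not called, and Tlr1 was lower (-0.98).

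Whether the fall of ribosome biogenesis genes at 10 h extends to related families was also tested. Cytosolic ribosomal protein genes did not show it: their median was 0.038 over 59 genes, with 4 higher and 3 lower (adjusted p = 0.0633, upward), and -0.004 after median centring. Their median level in untreated cells was 12.31, against 9.83, 9.19 and 10.7 for the 3 families that follow. Whether probe sets that bright would show a fall as well was not tested. Mitochondrial ribosomal protein genes were lower (median -0.151, 33 of 77 lower and 3 higher, adjusted p = 1.56e-11, and adjusted p = 0.057 with an estimated correlation). So were subunits of RNA polymerases I and III (median -0.097, 4 of 14 lower and 2 higher, adjusted p = 0.00872, and adjusted p = 0.14 with an estimated correlation) and cytosolic aminoacyl-tRNA synthetases (median -0.229, 8 of 18 lower and 1 higher, adjusted p = 8.95e-05, and adjusted p = 0.212 with an estimated correlation). A fall in ribosome assembly, mitochondrial ribosomal proteins, polymerase subunits and cytosolic aminoacyl-tRNA synthetases, but not in cytosolic ribosomal proteins, is left as a hypothesis. It was found and tested on the same data.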
